A study of Mus musculus with 2 samples.

How the data were processed

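DNase-seq was carried out on the left cerebral cortex of male B6CASTF1/J mice of 8 to 10 months, in 2 libraries labelled biological replicates 1 and 2. Both carry the same donor identifier and different biosample identifiers in the labels, and both were placed in 1 group. If that donor identifier stands for 1 animal, the SDs and the agreement of the replicates leave out variation between animals. Per the labels, the assay is credited to a laboratory at UW and the tissue to one at Caltech, and the files use the mm10 assembly. Analysis started from the processed files, and the reads were not analysed here.

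Peaks were called by the authors on each library alone, per the notes deposited with the files, and 2 peak lists per library were deposited. The peak caller and the aligner are not given in the sources used here. Each peak carries a deposited signal value, here called its strength, whose normalization is not given. Within a library all strength values were whole multiples of 1 step (tolerance 0.02 of a step), 0.00948 in replicate 1 and 0.00926 in replicate 2. If 1 step stands for 1 tag scaled by depth, an assumption, the libraries had nearly equal depth. The authors also deposited a table of FDR values (false discovery rates, a kind of q-value) for short intervals, which lists only values under 0.05. Every peak of the smaller peak list held an interval of that table at 0.001 or less, and every peak of the larger list held one at 0.05 or less. These are called narrow peaks and the broader list. Footprints were deposited as intervals, derived from the FDR table and the alignments per the same notes; their value column is constant and was not used. Strength was compared between libraries without further scaling.

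The designs, gene lists, consensus sequences and most alternatives were fixed before the data were examined. They assumed a set of broad accessible regions; no set of that kind was used here, and the broader peak list was used in its place. Coordinates are mm10, counted from 1. Genes, starts and sequence came from the GRCm38.p6 reference with GENCODE M21, whose chromosome names matched the files and whose chromosome ends no interval passed. The animals are hybrids, so alleles that differ from the reference could not be separated in these files. Unplaced sequences held no interval.

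Overlap meant at least 1 bp shared, set beside 100 circular shifts of replicate 2 along each chromosome, with replicate 1 left in place. Strength was correlated over peaks that overlapped exactly one peak of the other library. A peak or footprint was placed by its midpoint, first within 1000 bp of any annotated start, then in exon classes, introns or intergenic DNA, and genome shares were computed in the same order. A gene had a promoter peak where a narrow peak overlapped 1000 bp on either side of the start of any of its transcripts, so a peak between neighbouring genes counted for both. Peak density was the number of narrow peak midpoints per 10 kb over the gene and 10 kb on each side, and windows of neighbouring genes can share peaks. Peak counts printed for single genes are of narrow peaks in the same windows, before any joining unless stated. A gene without a narrow peak there may still hold a peak of the broader list. For each of 30 gene lists (515 of 522 members matched a protein-coding gene once), the median density was placed among 10000 random lists of the same size drawn from 20 bins of gene length. A list was called when it reached the 95th or the 5th percentile in both libraries. Counts of list members with a promoter peak need one in both libraries. The shares given for random lists are means of their single-library shares, an easier measure, so such pairs overstate a shortfall somewhat. Percentiles of promoter share compare each library with itself. With 2 libraries and no groups, no p-value was computed. Means are given with the SD over the 2 libraries, which is a rough estimate of spread at this number. For sharing between the libraries the SD is over the 2 directions of 1 comparison. It reflects the sizes of the 2 sets and does not measure how sharing varies. Gene families (8) were described without a call.

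Each of 31 consensus sequences was searched on both strands. The share of footprints holding the centre of a match was divided by that of windows of equal width moved 50 bp to either side that overlapped no footprint. A motif was called enriched when the fold was over 1.5 and its 95% interval, on the log scale from the counts, lay above 1 in both libraries. A control count of 0 was set to 3, and no fold was given when both counts were at most 3. The intervals cover counting error only.

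Genes and peaks were named by a rule. It took the 3 members of each list with the highest and the 1 with the lowest peak density, the 10 strongest shared peaks by the worse of the 2 within-library ranks, the 20 genes with the most peaks in the library where they had fewer, and the 5 strongest peaks of each library that overlap none of the other. It also took up to 4 members per list, by density or strength, that lacked a promoter peak in a list above the limit or had one in a list of another organ. Not every gene so named is printed, for brevity or because some items, 1 motif among them, are not reported here. Epor and the neighbouring genes at 3 promoters were named after their values were seen.

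The steps were tested on simulated data. An overlap simulated at 60.2% of 20000 intervals was recovered as 60.2%, and a motif planted in 19.1% of 9994 intervals as 19.2%. With 18 members and the real 21938 gene lengths, lists with unchanged density were called above in 0 of 100 simulations, lists with 2-fold density in 29 of 100 and lists with 4-fold density in 82 of 100, so a list without a call can still differ.

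Alternatives changed the strength threshold, the overlap rule, the distance to the start, the window, the statistic, the peak list, the motif control, the FDR limit and the replicate left out. Another 10 were chosen after seeing the data: use of the broader list for 4 results, narrow peaks against the other broader list, footprints inside a peak of both libraries, the broader list without starts for 2 results, and peaks within 200 bp joined for 2. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.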

Results

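Chromatin accessibility was measured by DNase-seq, in which DNase I cuts exposed DNA in nuclei and the cut ends are sequenced, in the left cerebral cortex of male B6CASTF1/J mice. These animals are first-generation hybrids between a laboratory strain and a wild-derived castaneus strain, and were 8 to 10 months old. The 2 libraries were labelled biological replicates 1 and 2 of 1 tissue, without a treatment or a second group. The comparisons were therefore between the replicates, and between classes of genes and sites within each library. Read totals were not used here. Replicates 1 and 2 held 40705 and 39508 narrow peaks (the stricter of the deposited lists), 71210 and 72217 peaks in the broader list, and 166128 and 174394 footprints, which are short protected stretches inside accessible DNA. Narrow peaks covered 8.99 ± 0.234 Mb (SD, n = 2 libraries), or 0.330% of the assembled chromosomes.

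Which gene groups carried many or few narrow peaks was asked against protein-coding genes of similar length. Activity-regulated genes, which neuronal firing induces, had the highest median density of the 30 lists tested, at 1.44 ± 0.190 (SD, n = 2) peaks per 10 kb against 0.362 in random lists. Housekeeping genes had 1.06 ± 0.0455 against 0.396, and circadian clock genes 0.792 ± 0.00306 against 0.294. Imprinted genes had 0.498 ± 0.0570 against 0.299, and pan-neuronal and synaptic genes 0.269 ± 0.00196 against 0.190. These were the 5 of 30 lists at or above the 95th percentile of 10000 random lists in both libraries. The percentiles describe these libraries and are not p-values, because genes are not replicates.

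In the activity-regulated list, 24 of 25 genes had a promoter peak in both libraries and the other had it in 1 library. Junb, a subunit of the AP-1 transcription factor, had 10 peaks in replicate 1 and 14 in replicate 2 over the gene and 10 kb on each side. Dusp6, a phosphatase that switches off ERK signalling, had 6 in each library. Homer1, a postsynaptic scaffold gene and the list's lowest by density, had 1 and 2, with a promoter peak of strength 4.63 ± 0.712 (SD, n = 2). Arc, which controls AMPA receptor trafficking, had 1 peak in replicate 1 and 11 in replicate 2, while its promoter peak had similar strength in both, 4.46 and 5.01. All 17 clock genes had a promoter peak in both libraries. Dbp, an output gene of the clock, had 11 peaks in each, Per1, a core repressor, had 16 and 9, and Bhlhe40 had 6 and 8. Rorb, the lowest clock gene by density, had 3 and 2. With peaks within 200 bp of each other joined, Junb had 8 in each library and Per1 11 and 9, while Arc still differed with 1 and 9.

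All 30 pan-neuronal and synaptic genes had a promoter peak in both libraries, against 74.4% in a single library for random lists. Vamp2, a synaptic vesicle SNARE gene, had 5 and 6 peaks, in a window that overlaps that of the neighbouring Per1. Dlg4, which encodes the scaffold PSD-95, had 7 and 6. The neurofilament gene Nefl had 5 and 2, or 2 and 1 with neighbouring peaks joined. The vesicle calcium sensor gene Syt1, which spans 513 kb, had 3 in each. This list's call ended with windows of 50 kb, where replicate 2 lay at the 94.4th percentile, and with neighbouring peaks joined, where it lay at the 92.4th. All 18 housekeeping genes had a promoter peak in both libraries. Their highest members were the tubulin gene Tubb5 with 4 and 8 peaks, Rpl19 with 8 and 2, and Hsp90ab1 with 6 and 4, and their lowest was Hprt with 2 in each. When peaks within 1000 bp of a start were left out, the housekeeping list lay at the 47.9th percentile in replicate 1 and the 98.9th in replicate 2, which ended its call; with the broader list without starts the call held.

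Of 23 imprinted genes, 16 had a promoter peak in both libraries. The cell cycle inhibitor gene Cdkn1c had 4 peaks in each library, Peg10 had 5 and Peg3 had 6. The other 7 genes had a promoter peak in neither, among them Nnat, Ndn, Igf2 and Kcnk9, which had 1 to 4 peaks elsewhere in their windows. Dlk1 had no narrow peak. The call for imprinted genes held in 4 of 10 other settings.

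Median density was 0 in both libraries for the ependymal and choroid plexus, heart, erythroid, and gut and pancreas lists. Their random lists had 0.319, 0.332, 0.346 and 0.333 peaks per 10 kb. These 4 lists lay at or below the 5th percentile in both libraries, with 7 such lists in replicate 2 alone and 6 in replicate 1 alone. All 4 calls ended with 50 kb windows, all but the first ended with the broader list, and that of erythroid genes ended with the mean in place of the median. All 4 held by promoter share, and by summed strength and with neighbouring peaks joined, where a median of 0 stays 0. With the gene body alone the 4 lists, and with the strongest 50% of peaks all but the first, had a median of 0 above the 5th percentile; that is the lowest possible value, so no call below could be made. Promoter peaks in both libraries were found for 3 of 16 ependymal and choroid plexus genes. Those included Foxj1, the main transcription factor of motile cilia, with 2 peaks in each library and a promoter strength of 4.71 ± 0.121 (SD, n = 2), and Rfx2, with 4 in each. Ccdc153 had 1 and 2 peaks, and the water channel gene Aqp1 had none. No heart gene of 14 had a promoter peak, although Gata4 had 2 peaks in each library, Myh6 had 2 and 1, and Nppa had 1 in each; Hand2 had none. Among 14 erythroid genes, Epor had a promoter peak in replicate 2 only and the others had none. The erythroid regulator Klf1 had 4 and 3 peaks, the globin gene Hba-a2 had 2 in each, and Alas2 had none. In the gut and pancreas list, 2 of 16 genes had a promoter peak in both libraries, Cela1 and Lgr5. The insulin gene Ins2 had 3 and 2 peaks without one, in a window that overlaps that of the imprinted gene Igf2. Lgals4 had 1 and 2 peaks, and the amylase gene Amy2a1 had none. With peaks near starts left out, no list lay at or below the 5th percentile; the random medians of these 4 lists were then 0.

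The remaining lists of other organs were not called by density of narrow peaks. Liver genes had a median density of 0.0975 ± 0.138 (SD, n = 2) against 0.350, skeletal muscle 0.215 in each library against 0.420, and lymphocyte 0.295 ± 0.0242 against 0.344. Germ line genes had 0.309 ± 0.00757 against 0.314, and kidney and lung genes 0.271 ± 0.0925 against 0.330. Liver genes lay below the limit in both libraries with the mean in place of the median, all 5 lists did by promoter share, and lymphocyte genes lay above, at the 98.5th and 98.3rd percentiles, with the broader list without starts. Promoter peaks were fewer than in random lists in each. They were found in both libraries for 0 of 19 liver, 3 of 17 skeletal muscle, 4 of 18 lymphocyte, 1 of 16 germ line, and 0 of 15 kidney and lung genes. Random lists had 49.4%, 49.3%, 55.6%, 52.2% and 54.3% in a single library. The strongest of these promoter peaks were those of Actn3, a muscle actinin gene, at 4.59 ± 0.420, Foxp3, the regulator of regulatory T cells, at 3.49 ± 0.197, and Mylpf, a muscle myosin light chain gene, at 3.09 ± 0.349. Another gene starts within 1000 bp of each of these 3 peaks (Zdhhc24, Ppp1r3f and Tbc1d10b), and of no other among the 10 genes of these organs, gut and pancreas included, with a promoter peak in both libraries. The other named members were Ckm at 2.42 ± 0.854, Lck at 1.51 ± 0.0317, Dazl at 1.13 ± 0.151, Cd22 at 0.802 ± 0.166 and Pax5 at 0.725 ± 0.0609.

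By density of narrow peaks over the gene and 10 kb on each side, no list for a single cell type of the cortex passed a limit in both libraries. Excitatory neuron genes had a median density of 0.308 ± 0.0522 (SD, n = 2) against 0.266 in random lists, upper layer genes 0.221 ± 0.0372 against 0.203, and deep layer genes 0.206 ± 0.0415 against 0.217. With the broader list without starts, excitatory neuron genes lay at the 98.1st and 99.9th percentiles. Tbr1, a transcription factor of deep layer neurons, had 10 and 13 peaks, Bhlhe22 had 4 in each, and Neurod6 had 1 and 7. Pou3f3, in the upper layer list, had 3 and 5 peaks and a promoter strength of 4.09 ± 0.0545, and Pou3f2 had 7 and 3. The windows of Fezf2 and Nptx1 held no narrow peak in either library, and that of Mef2c held 1 in replicate 1. Their peaks in the broader list are not given here. Inhibitory neuron genes had 0.0839 ± 0.0359 against 0.280, at the 1.79th percentile in replicate 1 and the 6.19th in replicate 2, and lay below the limit in both in 4 of 10 other settings. In the inhibitory list 4 of 22 genes had a promoter peak in both libraries; the GABA transporter gene Slc32a1 had 6 and 3 peaks, Maf had 5 in each, Sp9 had 1 and 6, and Dlx1 had none.

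Glial lists were close to their random lists in density of narrow peaks. Astrocyte genes had 0.250 ± 0.0326 (SD, n = 2) against 0.251, oligodendrocyte genes 0.325 ± 0.0371 against 0.327, oligodendrocyte precursor genes 0.258 ± 0.101 against 0.242, and microglia genes 0.361 ± 0.0824 against 0.362. With the broader list, astrocyte genes had 0.659 and 0.709 against 0.415 and 0.420, at the 96.4th and 97.9th percentiles. Promoter peaks in both libraries were found for 10 of 20 astrocyte, 5 of 20 oligodendrocyte, 8 of 15 precursor and 2 of 19 microglia genes. Random lists had 62.8%, 57.6%, 59.8% and 55.7% in a single library. By share in replicates 1 and 2, astrocyte genes lay at the 39.1st and 22.3rd percentiles and precursor genes at the 51.4th and 28.6th. Oligodendrocyte genes lay at the 12.5th and 0.62nd. Sox9 had 5 peaks in each library, Id4 had 4 and 6, and S1pr1 had 3 and 4. Olig1 had 4 in each and the myelin gene Cnp had 5 and 4, while Aspa had none. Olig2, the lineage transcription factor, had 5 peaks in replicate 1 and none in replicate 2, where its window held no interval of the FDR table against 1831 in replicate 1. Tyrobp had 1 and 3 peaks, Aif1 had 2 and 1, and the receptor gene Csf1r had none. With peaks within 1000 bp of a start left out, oligodendrocyte genes had 0.318 and 0.250 peaks per 10 kb and microglia genes 0.232 and 0.202, against random medians of 0. Both lists then lay above the 95th percentile in both libraries, microglia at the 99.5th and 99.4th; with the broader list without starts oligodendrocyte genes stayed above, and microglia genes were at the 98.7th and 89.3rd. By promoter share in place of density, microglia genes lay at percentile 0 in both libraries.

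Vascular and meningeal lists did not pass a limit in both libraries by density of narrow peaks. Pericyte and smooth muscle genes had 0.0944 ± 0.133 (SD, n = 2) against 0.317, meningeal and fibroblast genes 0.137 ± 0.0712 against 0.321, and endothelial genes 0.247 ± 0.0201 against 0.276. The endothelial list lay at the 30.9th and 44.5th percentiles. With the strongest 50% of narrow peaks, and by promoter share, all 3 lists lay below the 5th percentile in both libraries, as did the first and the last by summed strength and the meningeal list with 50 kb windows. With the broader list without starts, the endothelial list lay above, at the 95.9th and 96.6th. Promoter peaks in both libraries were present at 1 of 14, 3 of 14 and 4 of 18 of these genes, against 58.9%, 60.7% and 60.3% in a single library for random lists. Slc2a1, the glucose transporter of the blood-brain barrier, had 5 and 2 peaks, Vtn had 4 in each, Notch3 had 4 and 5, and Col1a1 had 3 in each. The tight junction gene Cldn5, the potassium channel subunit gene Abcc9 and Col3a1 had none.

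Lists named for other brain regions were not called either by density of narrow peaks. Striatum genes had a median density of 0.264 in each library against 0.265, thalamus genes 0.277 ± 0.0861 (SD, n = 2) against 0.245, and dentate gyrus genes 0.158 ± 0.0278 against 0.249. Cerebellum genes had 0.116 ± 0.0420 against 0.264, and midbrain and hindbrain genes 0.0674 ± 0.0560 against 0.311. Promoter peaks in both libraries were found for 8 of 13, 3 of 10, 3 of 10, 8 of 15 and 4 of 16 genes, in that order. Random lists had 60.2%, 64.7%, 67.3%, 52.2% and 54.5% in a single library. By promoter share the thalamus, dentate gyrus, and midbrain and hindbrain lists lay below the limit in both libraries, as did dentate gyrus genes with the strongest 50% of peaks and midbrain and hindbrain genes by summed strength. With the broader list without starts, thalamus genes lay above at the 97.1st and 98.1st percentiles, and midbrain and hindbrain genes at the 98.3rd and 99.0th. Ppp1r1b, which encodes DARPP-32, had 4 and 3 peaks, and Cbln1 had 2 and 5. En2 and Pitx3 had 3 in each library, and Isl1 and En1 had none.

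**Figure D1:**
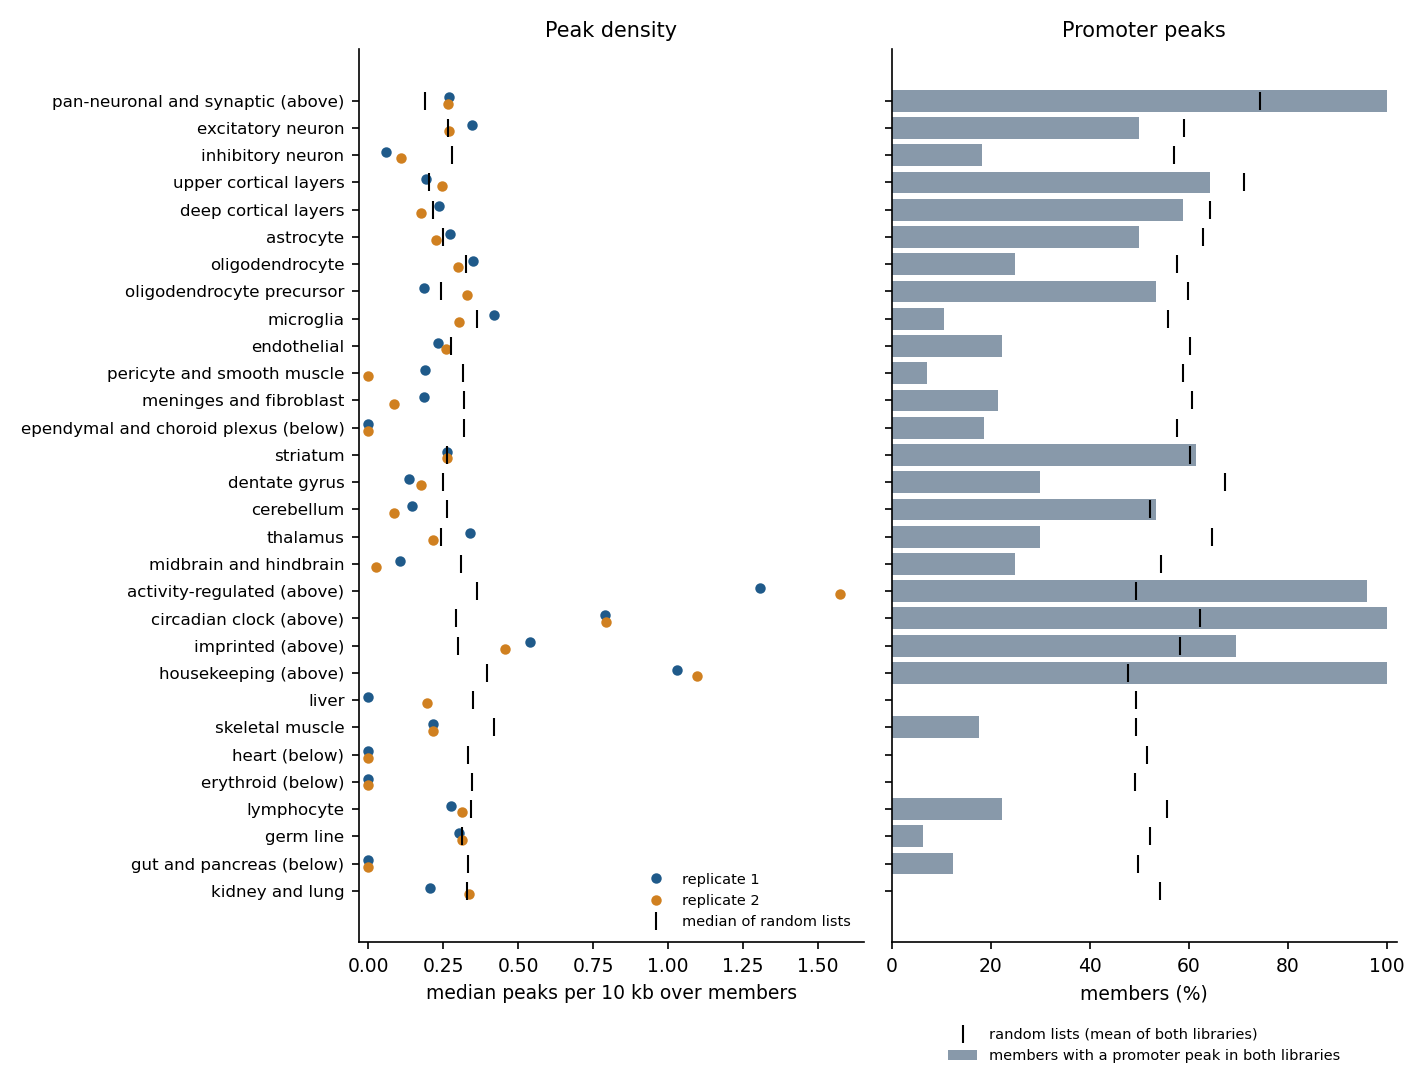
Left, median narrow peaks per 10 kb over the members of each of the 30 gene lists in replicate 1 and replicate 2 (points), with the median of length-matched random lists (black ticks). Right, percent of members with a promoter peak in both libraries (bars), with the mean single-library percent of the random lists (black ticks), an easier measure. Activity-regulated, clock, housekeeping and pan-neuronal genes show promoter peaks at 96.0% to 100% of members, and liver, heart, erythroid, and kidney and lung genes at 0%.

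The genes with the most narrow peaks, counted over the gene and 10 kb on each side, were mostly long. Gm20388, a gene model of 4435 kb that covers many other genes on chromosome 8, had 192 and 172 peaks, and Fgfr2, annotated over 2961 kb, had 76 and 79. Mid1, a gene of 321 kb (X:169685199-170005736) that spans the pseudoautosomal boundary in laboratory mice, had 35 and 41 peaks. Camta1 had 32 and 34, Auts2 23 and 27, Pde4d 23 and 22, Maml3 20 and 21, and Dlg2, a postsynaptic scaffold gene of 1973 kb, 21 and 19. Gse1, Asic2, Lsamp, Magi2 and Mast4 had 16 to 21 in each library. The long gene model Gm37240 had 22 and 25 peaks, and Gm37013, Gm37388 and Gm42416, overlapping models on chromosome 18, shared the same 19 and 25. Shorter genes among these 20 were Nfic, a nuclear factor I gene of 59.5 kb, with 19 and 30 peaks, and Mxd4, a MAX partner gene of 13.8 kb, with 17 and 15. Over the gene and its flanks, Mxd4 had 4.73 ± 0.418 (SD, n = 2) peaks per 10 kb. Part of such counts came from calls within 200 bp of each other. With those joined, Mxd4 had 9 and 7, Mid1 25 and 24, and Nfic 17 and 21, while Gse1 had 19 in each library.

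Narrow peaks lay near gene starts far more often than the genome share of such positions. Within 1000 bp of an annotated start lay 50.4% of the peaks of replicate 1 and 53.9% of those of replicate 2, a mean of 52.2 ± 2.47% (SD, n = 2) against 6.05% of the genome, which is 8.62-fold. Introns held 20.7 ± 1.65% of peaks and intergenic DNA 23.4 ± 0.933%, which is 0.541-fold and 0.446-fold their genome shares; each difference from the genome share exceeded the spread between the libraries. Median strength near starts was 1.62 and 1.44 in replicates 1 and 2, against 1.03 and 0.944 elsewhere. Of 21938 protein-coding genes, 12042 (54.9%) had a promoter peak in both libraries, 443 in replicate 1 only, 475 in replicate 2 only and 8978 in neither.

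The replicates shared most peaks, and nearly all strong ones. In replicate 1, 76.5% of narrow peaks overlapped a narrow peak of replicate 2 by at least 1 bp, and 78.4% in the other direction, a mean of 77.4% (SD of the 2 directions 1.37%). After 100 circular shifts along the chromosomes the mean was 0.683% and the highest 0.814%. Sharing rose from 46.3% and 44.0% in the weakest 20% of peaks to 99.2% and 99.6% in the strongest 20%. Against the other library's broader list, 91.3% and 90.3% of narrow peaks overlapped a peak. Near starts 85.2% and 81.4% of peaks were shared, and elsewhere 67.6% and 74.9%. Over 27311 one-to-one shared peaks, Spearman's rho of strength was 0.937, and 0.915 to 0.944 on single chromosomes; sites are not independent replicates, so no p is given. The median log2 ratio of replicate 2 over replicate 1 was -0.12 with an SD of 0.33 across sites, and 99.5% of pairs were within 2-fold.

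**Figure D2:**
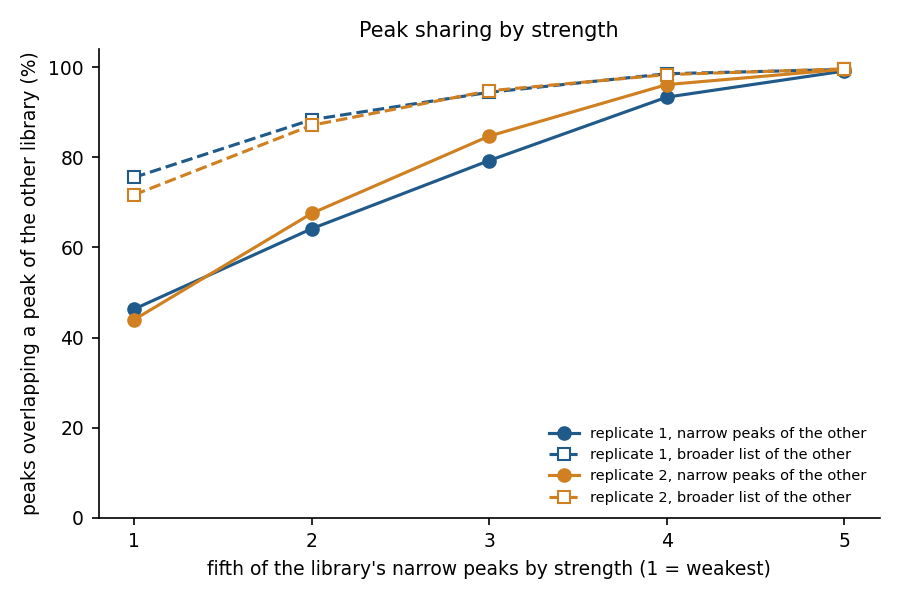
Percent of narrow peaks that overlap a peak of the other library, by 20% groups of strength within each library (x axis, 1 is the weakest), for replicate 1 and replicate 2 against the other library's narrow peaks (filled circles) and broader list (open squares). The weakest group reaches 46.3% and 44.0% against narrow peaks and 75.6% and 71.7% against the broader list, and the strongest group is above 99% on every line.

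The 10 strongest shared peaks were mostly not at protein-coding gene starts. They are given in the order of the worse of their ranks in the 2 libraries. The peak at 17:39846781-39846920, in an exon of CT010467.1 and 107 bp from the start of the lincRNA gene Gm42418, had a strength of 76.6 ± 25.6 (SD, n = 2). An intergenic peak at 3:5860361-5860530 had 39.4 ± 7.76, and one at 9:123461881-123462140 in the 3' UTR of Lars2 41.0 ± 12.1. Another intergenic peak at 6:49236421-49236640 had 31.2 ± 12.2, one at 16:11144171-11144320 in an intron of Zc3h7a 24.5 ± 8.29, and one at 15:99735661-99736060 in the 3' UTR of Cers5 23.98 ± 0.304. The others lay in an intron of Il31ra, an exon of Gm15564 and Kpna1, an intron of Gphn, and outside genes at 8:20424721-20424940, with 23.4 ± 11.0, 19.6 ± 5.70, 16.0 ± 4.95 and 13.04 ± 1.02. Starts of genes that are not protein-coding lay 121 bp from the Zc3h7a peak (Gm23935), 610 bp from the Kpna1 peak (Gm15564) and 17 bp from the chromosome 8 peak (2610005L07Rik). By the rule of 1000 bp these also count as near a start. In 9 of the 10, over 50% of the 24-base words occur elsewhere in the assembly, the Cers5 peak being the exception at 0%.

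Narrow peaks that overlapped none of the other library numbered 9579 in replicate 1 and 8534 in replicate 2, and 64.3% and 56.8% of them overlapped a peak of the other's broader list. The strongest of replicate 1 was in the 5' UTR of 0610009B22Rik (11:51688601-51688820, strength 6.99), followed by peaks at Pop7, 1700064H15Rik, Yeats4 and Rap2a with strengths of 4.58 to 4.44. The strongest of replicate 2 lay 137 bp from the same 0610009B22Rik start (11:51688861-51689160, 5.17), followed by peaks near Mxd4, Cfap126, Ppp2r3d and Nudt9 with 3.71 to 3.37. Each of these 10 lay 0 to 100 bp from a peak of the other library.

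The X chromosome, present in 1 copy in males, had fewer peaks than any autosome. Its density was 6.88 ± 0.0476 (SD, n = 2) narrow peaks per Mb, against 12.8 ± 0.0271 on chromosome 3, the lowest autosome, and 24.3 ± 0.595 on chromosome 11, the highest. The ratio of X to all autosomes was 0.414 and 0.432, a mean of 0.423 ± 0.0122, and among the strongest 50% of peaks it was 0.241. On X, 46.9% and 47.3% of protein-coding genes had a broader-list peak within 1000 bp of a start, against 63.6% and 64.1% on autosomes. The Y chromosome had 16 and 18 peaks. No female sample was measured, so sex was not compared.

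**Figure D3:**
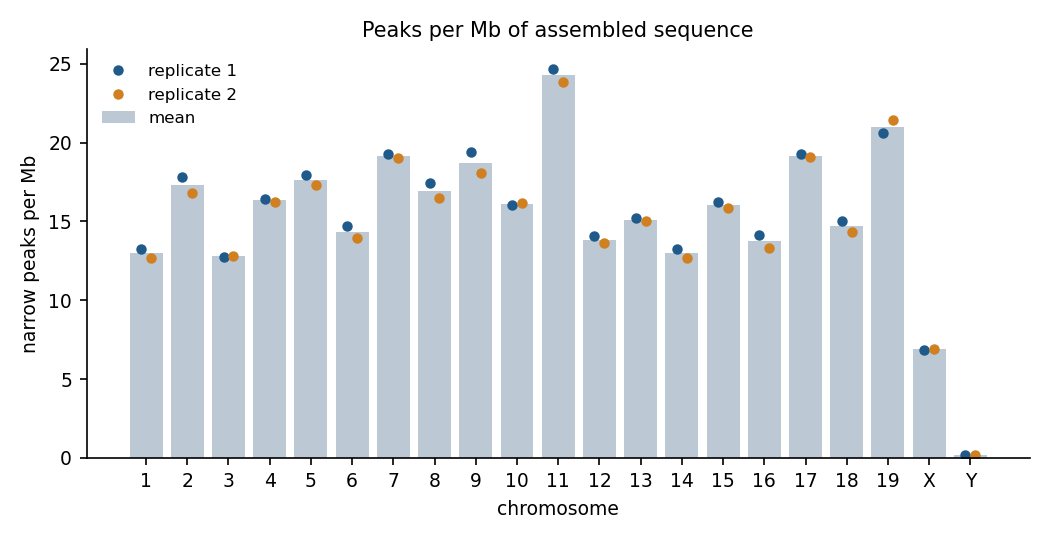
Narrow peaks per Mb of assembled sequence (y axis) on each chromosome (x axis), as the mean of both libraries (bars) with replicate 1 and replicate 2 (points). The X chromosome stands at 6.88 and the autosomes at 12.8 to 24.3.

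By the 1 bp rule footprints were shared less often than peaks. The median footprint was 9 bp wide and the median narrow peak 200 and 206 bp in replicates 1 and 2. Equal shifts of an edge thus end more overlaps of footprints, and the 2 shares are not on an equal measure. A footprint of the other library overlapped 46.0% of those of replicate 1 and 43.6% of those of replicate 2. The mean was 44.8% (SD of the 2 directions 1.70%), against 0.148% after circular shifts. Moving the footprints of replicate 2 by 50 bp gave 21.8% and by 100 bp 17.1%. Within narrow peaks lay 66.7% and 63.5% of footprints by midpoint, and 86.0% and 82.9% of narrow peaks held at least 1 footprint. Of footprints, 56.0 ± 1.77% (SD, n = 2) lay within 1000 bp of a start.

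Consensus sequences of 31 transcription factors or families were searched in footprints and in windows of the same width moved 50 bp, and 11 were enriched in both libraries. CTCF, the insulator and loop-anchor protein, had the highest fold, 87.95 ± 7.62 (SD, n = 2), with a match in 2.11% of footprints. NRF1, a regulator of mitochondrial and other basic genes, followed at 62.2 ± 10.0. Others of general function were RFX at 6.81 ± 0.319, SP/KLF at 6.51 ± 0.0623, the E-box of USF at 5.77 ± 0.541, YY1 at 3.41 ± 0.0779 and ETS at 1.70 ± 0.0822. Of the activity-linked motifs, the CRE bound by CREB had 13.5 ± 0.953 and EGR 8.82 ± 0.0343, while AP-1 had 0.958 ± 0.0233 and was not enriched. Of 9 motifs in the neural class 2 were enriched, NFI at 13.4 ± 6.98, from only 24 and 22 footprints with a match, and NEUROD at 3.51 ± 0.131. The MEF2 motif had 0.656 ± 0.103 and the SOX motif 0.453 ± 0.198. The size of a fold depended on the control. With windows moved 100 bp the 11 stayed enriched, but CTCF had 290 and 121, NRF1 113 and 58.6, the E-box of USF 11.1 and 7.04, and NFI 39.7 and 36.0 in replicates 1 and 2; only 22 and 45 control windows then matched CTCF, and 1 in each library matched NFI.

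Against the windows moved 50 bp neither microglial motif was enriched, with PU.1 at 0.787 ± 0.117 (SD, n = 2) and IRF at 0.616 ± 0.0610, nor was any of 8 motifs of other tissues, among them GATA at 0.531 ± 0.0508 and FOX at 0.293 ± 0.0572. HNF1 and REST had at most 1 footprint with a match in each library, too few for a fold. Footprints were richer in G and C than the moved windows, with 64.6 ± 0.107% against 55.8 ± 0.0870%. Against the consensus written backwards in the same footprints, 21 motifs passed and 9 of the 11 were kept. Writing it backwards keeps its base composition but not neighbouring pairs such as CG, which the CRE consensus loses. EGR fell to 1.29-fold and 1.24-fold, and SP/KLF reads the same backwards and has no such value. For several motifs not enriched over the moved windows the call turned with this control, as for AP-1 at 1.75 and 1.70, MEF2 at 3.56 and 3.67, SOX at 2.57 and 2.08, and PU.1 at 4.82 and 4.10. Of the motifs of other tissues, HNF4 (10.5 and 4.25), TEAD (2.95 and 2.32), glucocorticoid receptor and HSF also passed. The HNF4 values rest on only 2 and 4 footprints with a backward match in replicates 1 and 2.

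**Figure D4:**
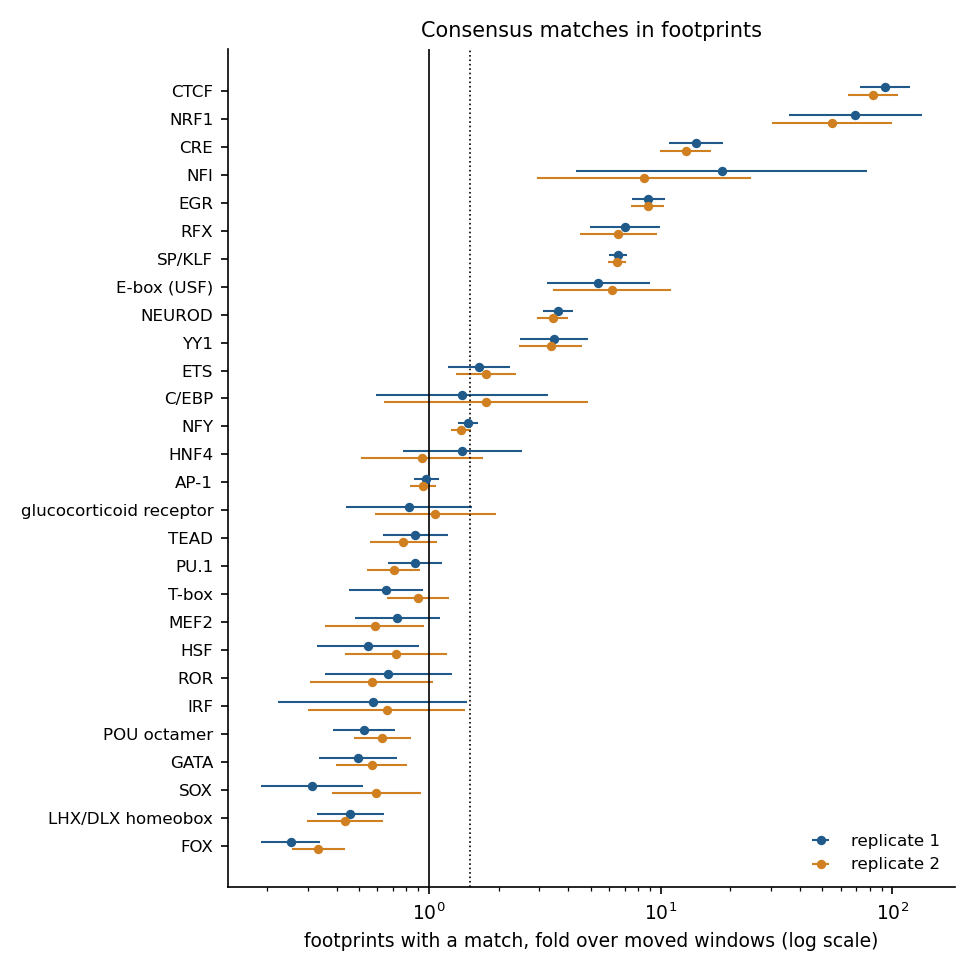
Share of footprints with a consensus match over the share of windows moved 50 bp (x axis, log scale), for replicate 1 and replicate 2 (points) with 95% intervals that cover counting error only; the solid line marks 1 and the dotted line 1.5. CTCF and NRF1 lie highest, with means of 87.95 and 62.2, and FOX lies lowest at 0.293.

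The per-interval table of false discovery rates (FDR) held 13091447 and 13798179 intervals at 0.05 or less, which covered 24.1 and 25.6 Mb in replicates 1 and 2. Of the covered bases, 80.7% of replicate 1 and 76.0% of replicate 2 were shared, a mean of 78.4% (SD of the 2 directions 3.30%). At 0.001 the table held 8684137 and 8904812 intervals. Neighbourhoods of single genes differed more: the Arc window held 752 intervals in replicate 1 and 4248 in replicate 2, the Rpl19 window 2239 and 697, the Sp9 window 103 and 2625, and the Neurod6 window 592 and 1508. These windows were chosen after their values were seen.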

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

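Chosen only after the result was seen were the tests with the broader list for peak sharing, strength and gene lists, narrow peaks against it, footprints inside peaks of both libraries and joined peaks. Over 12 results, 66 alternatives were run. Of these, 39 stayed within the spread set for the result or within 1.5 times the count, and 27 moved. The spread was the SD between the libraries, for sharing that of the 2 directions, and for the strength correlation that between 20 chromosomes. Of the 18 that left out a replicate, 1 moved: lists below the 5th percentile numbered 6 to 7 with a single library, against 4 in both. For coverage, the share near starts, the X ratio and footprints inside peaks, leaving out a replicate could not count as moved. Either of 2 values always lies within their SD of their mean, so these tests do not show stability. With the strongest 50% of narrow peaks, peak sharing was 86.7%, the strength correlation 0.880, the share near starts 64.1%, the X ratio 0.241 and footprints inside peaks 46.7%. Requiring 50% overlap of both gave 60.4% of peaks and 31.9% of footprints shared. The broader list gave 73.6% of peaks shared, 40.4% near starts, 87.0% of footprints inside peaks and 1 list below; narrow peaks against the other broader list were shared at 90.8%, and narrow peaks covered 8.99 Mb against 16.1 Mb of the broader list. Distances of 500 and 2500 bp put 44.8% and 59.6% of peaks near starts. Footprints inside a peak of both libraries were shared at 61.9%, against 28.6% after a move of 50 bp. With 50 kb windows 3 lists lay above and 2 below. With the gene body alone, 0 lay below. Without peaks near starts 0 lay below. In both, many lists had a median of 0, the lowest possible, above the 5th percentile and could not be called below. With the broader list without starts 10 lay above and 0 below. The promoter share put 17 lists below, and summed strength 8. The backwards consensus gave 21 motifs, and an FDR limit of 0.001 gave 8794474.5 intervals on average. The cause of these moves was not tested, except that a larger overlap or distance changes what is counted by construction. Promoter genes in both libraries ranged from 10261 to 13338. The 2 alternatives on the strongest footprints were not run, because the files give footprints no score. No paired analysis was possible because there is 1 group only.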

Other observations

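In this part, the tests of gene density on the X chromosome, of the local calling limit and of peak calls near starts were chosen only after the result, or examples of it, were seen. The range set for a single X copy was reworded before its value was computed, and the pattern of replicate differences was widened after its first 2 tests.

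Large gene families differed widely in promoter peaks. All 72 ribosomal protein genes had one in both libraries, as did 326 of 391 Zfp zinc finger genes. In contrast, 1 of 1093 olfactory receptor genes, 1 of 327 vomeronasal receptor genes and 1 of 39 Hox genes had one, with a median density of 0 peaks per 10 kb in each of these 3 families. Keratin genes had a promoter peak in both libraries at 4 of 49 and defensin genes at 2 of 66. Clustered protocadherin genes, which neurons express in varied combinations, had a promoter peak at 8.77% of 57 members in replicate 1 and 15.8% in replicate 2, with median densities of 0.257 and 0.421.

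The X chromosome carried 0.423 ± 0.0122 (SD, n = 2) of the autosomal density of narrow peaks. A lower gene density is argued against as the whole cause, since X had 1.19 ± 0.00820 peaks per protein-coding gene against 1.34 on the lowest autosome. More repeat-masked sequence is argued against too, since X had 12.9 ± 0.0893 peaks per unmasked Mb against 19.8 on the lowest autosome. Over genes with a broader-list promoter peak, median promoter strength on X was 0.517 ± 0.00289 of that on autosomes, which is consistent with a single X copy that puts more X sites under a fixed limit. That value covers only sites strong enough to be called, and with no female sample a true regulatory difference of X stays open and untested.

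The 10 strongest shared peaks lay mostly away from protein-coding starts. Their median share of 24-base words found elsewhere in the assembly was 75.6%, against 0% over 200 random shared peaks. Signal from several copies placed at one site is thus a candidate explanation for 9 of them. The copies counted were few: at most 2 per word at the strongest peak, and medians of 3 to 9, at most 18, at the others of the 9. Strengths of these 9 were 13.04 to 76.6, against library medians of 1.22 and 1.15. Whether these copies suffice was not tested, and copies missing from the assembly could not be counted. Words of the mitochondrial genome were found in 0 of the 10, which argues against nuclear copies of that genome as the source. The Cers5 peak, with 0% of its words elsewhere, stays unexplained, and no biological explanation was tested.

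The replicates differed at some neighbourhoods far more than in shared peaks, as at Arc with 1 and 11 peaks and Olig2 with 5 and 0. In 61 tiles of 50 kb at least 4 narrow peaks of replicate 1 were absent from the broader list of replicate 2 (permuted mean 9.64, highest 17), and in 96 tiles the reverse held (17.8, highest 27). The peaks missing from the other library in these tiles were weak. Their median strength was 0.389 in replicate 1 and 0.417 in replicate 2, against 1.22 and 1.15 over all narrow peaks of each library. A shift in strength between promoters and other sites was too small at shared peaks, with log2 medians that differed by -0.0319, but a shift in calls was not excluded. Of narrow peaks without a narrow peak of the other library, 31.7% and 46.5% in replicates 1 and 2 lay near starts. Of those absent from the other's broader list, 42.5% and 54.6% did. Of the latter peaks in the tiles, 35.1% and 30.0% did, a difference of -5.17 points, the other way. A different mixture of cell types could not be excluded either, since 1 of 6 brain cell lists, excitatory neurons at the 98.5th percentile, lay beyond the limits. In all, 4 of 29 lists did, each towards higher strength in replicate 2. The other members of these 4 were midbrain and hindbrain genes at percentile 100, erythroid genes at 99.3 and upper layer genes at 99.2. At shared peaks in those tiles the median log2 ratio lay within 0.0243 of the genome-wide one, so a calling limit that differs from place to place may account for part of the missing peaks; that test was written after 5 such neighbourhoods had been looked at, and shared peaks passed both limits by construction, so a true local difference at the missing sites stays open.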
